A study of Larix kaempferi with 6 samples.

How the data were processed

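RNA-seq was carried out on the upper 3 cm of 4-month-old seedlings of Larix kaempferi (Japanese larch, a deciduous conifer), in 3 libraries from watered controls and 3 libraries from seedlings left 14 d without watering. Per the labels' protocols, seedlings were grown singly in pots in a greenhouse at a soil water content of at least 70% of field capacity before the treatment, tissue was flash frozen, total RNA was used, and libraries followed standard Illumina protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say that each library came from a separate plant, so the p-values measure the spread between these libraries, which may be partly technical.

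The authors deposited one table per library with an identifier and an FPKM value (fragments scaled to transcript length and library size, named per the file headers), rounded to 2 decimals, for the same 12228 transcripts. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT2 2.1.0 and HTSeq 0.6.0 were used, with no role given for each. The counting rule, the use of strand, the treatment of fragments that match several transcripts, any filter on transcripts, and how FPKM was computed are not given in the sources used here. The series title describes long-read isoform sequencing, and the identifiers have the form Lo_f, p, a number, transcript and g. The files do not pair identifiers with gene names, and no genome, annotation or name table was used here, so the gene lists set up beforehand could not be matched and no gene function, chromosome or coordinate is given. The meaning of the g field is not stated, so no comparison of isoforms within a locus was made.

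FPKM values are relative: a rise of some transcripts lowers the values of all others. Depth was estimated from the steps of the low values. If a library's values are whole numbers of fragments divided by a length, then low values times that length should fall on multiples of one step. The length was taken as the number before "transcript" in the identifier, which runs from 126 to 4303 (median 1172.5), minus an offset fitted per library. The best offset was 280 nt in 3 libraries and 290 nt in the other 3. With it, 66.0% to 70.7% of the values worth under 6 fragments came out whole within 0.1 fragment, against 18.6% to 19.6% when lengths were shuffled between transcripts. These shares cover only the 241 to 347 such values per library for which rounding to 2 decimals matters little. Offset and step were not refitted to the shuffled lengths, so the shuffled shares may be too low. That number was therefore treated as the transcript length in nt. The remaining low values were not whole, so whole reads could not be recovered for nearly all transcripts and no test of read counts was run. A fit to the estimated fragments (limma-voom) was run only as an alternative. The steps correspond to 12800000 to 17200000 fragments per library, and 1 fragment on a transcript of 1200 nt was worth 0.0630 to 0.0857 FPKM. These depths are estimates, and no counting intervals are attached to single FPKM values.

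The main comparison had been set up for counts, with a fallback for normalized values that was then used: limma's moderated test with a mean-variance trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), drought against control, all 6 libraries, no covariate. The filter, chosen once the unit was known, kept the 9317 transcripts with an FPKM of at least 1 in at least 3 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low transcripts. Single values per library were compared by exact two-sided permutation tests (scipy 1.17.1). With 3 libraries against 3, the smallest p these can give is 0.1. The transcripts named were chosen by a rule fixed before the data were examined: the 2 with the smallest p in each direction, among those past the threshold with a mean log2 value of at least 1 and no overlap between groups.

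Libraries were compared pairwise by Pearson correlation of log2(FPKM + 1) and by the ratio of the observed variance to that of fragment counting, using the estimated fragments of transcripts over 500 nt with more than 50 fragments in the pair. That ratio is the median squared deviation divided by its value under counting noise alone, with a 95% interval from 500 bootstrap draws over transcripts. Fragments shared between similar transcripts and PCR copies both raise it. The replicate numbers were checked for pairing: the correlations of deviations from the group means were -0.15, 0.23 and -0.03 for numbers 1, 2 and 3, so the numbers were not taken to pair libraries.

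The fit was tested on simulated data with the means and spread of the 9317 transcripts, in which 200 were changed. It called 10% of the 2-fold, 68% of the 4-fold, 92% of the 8-fold and 98% of the 16-fold changes (5, 34, 46 and 49 of 50 each). It also called 14 of 9117 unchanged transcripts. Set against the 5, 34, 46 and 49 true calls, these 14 make up more of all calls than the threshold of 0.05 aims at. This was a single simulated set. Far fewer transcripts were changed than were called in the data, and the adjustment depends on that share. The noise was independent between libraries and held no length trend, so these shares may not carry over. In 20 simulated sets with no change, the median number of calls was 0, and an unadjusted p under 0.05 was reached by 4.83% of transcripts. When control 2 was simulated as a near copy of control 1, that share was 11.7%.

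Alternatives planned before the data were examined were other scalings (median-of-ratios factors, upper quartile factors, equal FPKM sums), no filter, a filter at an FPKM of 10, robust variance estimation, the replicate number as a block, each library left out in turn, the 100 most abundant transcripts left out, a threshold of 0.01 and a test against a 1.5-fold change. The main plan assumed counts, so settings stated in FPKM were adapted once the unit was known. Alternatives added after seeing the data were pseudocounts of 0.1 and 10, quantile normalization, no mean-variance trend, limma-voom on the estimated fragments, controls 1 and 2 averaged into 1 sample, and 3 ways of treating a length trend between libraries: a loess curve against log length removed from each library (span 0.5), a term for the 2 libraries that lose long transcripts, and the other 4 libraries alone. Removing the loess curve also removes each library's overall offset, so it acts partly as a rescaling, and these effects were not separated. Models of raw counts and thinning to equal depth were planned and not run, because the deposited values are not counts.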

Results

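The transcriptome of larch shoot tips was compared between 3 watered seedling libraries and 3 libraries from seedlings left 14 d without watering. Values were available for 12228 long-read transcripts. Between 9530 and 9654 of them had an FPKM above 0 in each library, and 9169 were above 0 in all 6. A further 2298 transcripts (18.8%) were listed at 0 in every library. The FPKM values summed to 1080454, 1074213 and 1237913 in controls 1 to 3 and to 1169511, 1046332 and 1037936 in drought 1 to 3. The estimated depth was 14200000, 14100000 and 17200000 fragments in the controls and 14600000, 14300000 and 12800000 in the drought libraries, to the nearest 100000. The transcripts carry no gene names here, so the response is described by transcript numbers, levels and lengths.

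The first question was whether libraries group by watering. The first principal component of log2(FPKM + 1) held 61.2% of the variance and placed the 3 controls between -0.612 and -0.598 and the 3 drought libraries between 0.357 and 0.749. Libraries of different groups correlated at r = 0.740 to 0.822 across transcripts (9 pairs). Libraries of the same group correlated at 0.893 to 0.989 among controls and at 0.877 to 0.961 among drought libraries (3 pairs each). Transcripts are not independent replicates, so these correlations describe the libraries only.

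Libraries within a group were unevenly spaced. Controls 1 and 2 correlated at r = 0.989, with 118 of 9317 transcripts (1.27%) at least 2-fold apart. Control 3 was at least 2-fold from control 1 in 2434 transcripts and from control 2 in 2510. From the mean of controls 1 and 2 it was at least 2-fold away in 2422 transcripts, and in 1533 once the length trend described below was removed. That removal also takes out a library-wide offset of control 3. The SD of the log2 difference moved only from 0.955 to 0.909, so the fall to 1533 cannot be credited to length alone. The variance between controls 1 and 2 was 2.47 times that of fragment counting (95% interval 2.34 to 2.64), and it was 20.2 to 68.3 times in the other same-group pairs. Controls 1 and 2 are labelled as separate samples and were kept as 2. The labels do not show that they are independent, and the counts with both averaged into 1 sample are given beside the main ones. Drought 3 correlated with the controls at r = 0.803 to 0.822, and drought 1 and 2 at 0.740 to 0.769. The second component, with 19.9% of the variance, set control 3 (0.692) apart from controls 1 and 2 (-0.339 and -0.347).

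**Figure D1:**
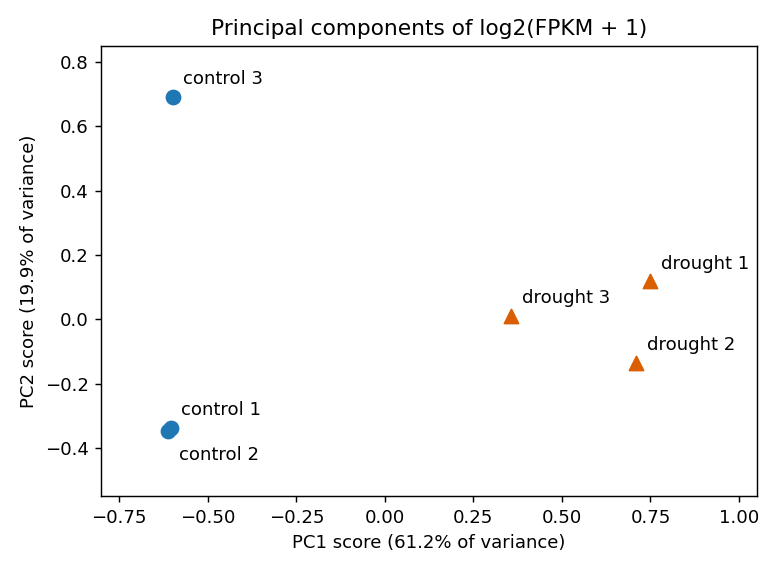
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over 9317 transcripts, with circles for controls and triangles for drought libraries. The groups separate along the first component (61.2% of variance), controls 1 and 2 nearly coincide, and drought 3 sits at 0.357, between the controls and the other drought libraries.

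Drought libraries differed from controls in transcripts that rose and in transcripts that fell. Of 9317 transcripts, 955 (10.3%) were higher and 905 (9.71%) were lower after 14 d without watering, and 7457 did not pass the test (limma's moderated test, Benjamini-Hochberg adjusted p under 0.05). The median change was 3.02-fold among risen transcripts and 3.34-fold among fallen ones. A change of at least 2-fold was reached by 807 risen and 828 fallen transcripts (1635 in all), of at least 4-fold by 342 and 345, and of at least 16-fold by 87 and 42.

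The risen transcripts moved from a median control level of 25.5 FPKM to a median drought level of 97.9 FPKM, and the fallen ones from 65.4 to 15.6 FPKM. Risen transcripts held 5.88% ± 0.96 (SD, n = 3) of all FPKM in controls and 21.8% ± 3.20 in drought libraries. Fallen transcripts held 15.2% ± 0.61 in controls and 4.75% ± 0.82 in drought libraries. These sets were chosen on the same libraries, so the shares describe them and are no separate evidence. By library, the risen set held 24.4%, 22.8% and 18.2% in drought 1, 2 and 3.

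Calls were found in every class of mean level. The classes were cut on the mean of the log values used in the fit, turned back into FPKM. Such a mean lies below the plain mean FPKM when groups differ, so strongly changed transcripts were moved towards the lower classes. The counts therefore do not show how calls depend on plain mean FPKM. Among 1661 transcripts with a mean level under 10 FPKM on this scale, 127 rose and 203 fell. Among 4034 between 10 and 50 FPKM, 371 rose and 368 fell, and among 3622 over 50 FPKM, 457 rose and 334 fell. The drought and control values of 3894 tested transcripts (41.8%) did not overlap, 2149 of them higher and 1745 lower in drought. Chance gives 10% for 3 independent libraries against 3, and the other 9 splits of the libraries gave at most 15.5%. Those splits mix control and drought libraries in each arm, so a difference between the groups itself lowers their share. Independence is open for controls 1 and 2. Of these other splits, those that keep controls 1 and 2 together gave 7.28% to 15.5%, and those that part them 0.77% to 6.93%.

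The number of calls depended on single libraries. With controls 1 and 2 averaged, 919 transcripts passed (490 higher, 429 lower), and all 919 were among the 1860. Leaving out control 1, control 2, drought 1 or drought 2 gave 931, 914, 1041 and 742 calls. Leaving out control 3 gave 2623 calls (1098 higher, 1525 lower), and leaving out drought 3 gave 1948. Without control 3 the control arm is the closely spaced controls 1 and 2 alone, and 1 of the 2 libraries with a loss of long transcripts is gone, and the parts these play in the 2623 calls were not separated. The balance also moved with the scaling, from 890 higher and 698 lower at equal FPKM sums to 1038 and 1143 with upper quartile factors. Each of the 1860 transcripts kept the direction of its change in all of these comparisons. The control and drought values of all 955 risen and all 905 fallen transcripts did not overlap. Leaving out or averaging libraries therefore could not turn a direction, and only the scalings could have. The median log2 change of all tested transcripts was 0.055 in the main fit. It was -0.029 with upper quartile factors and 0.110 at equal FPKM sums. As 1635 of the 1860 had changed at least 2-fold, most directions were close to assured under the scalings too.

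**Figure D2:**
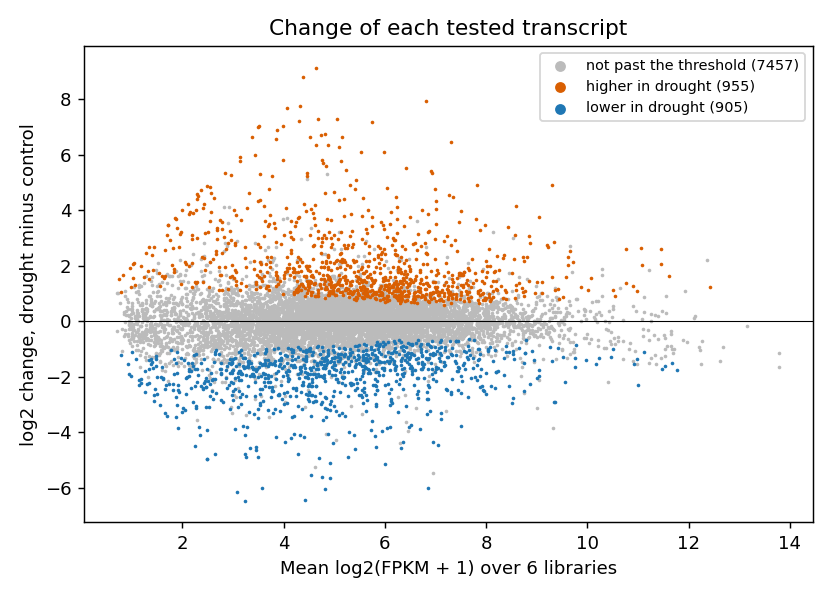
Log2 change (drought minus control, on the log2(FPKM + 1) scale) of each of the 9317 tested transcripts against its mean log2(FPKM + 1) over the 6 libraries. Orange points are the 955 transcripts higher in drought, blue points the 905 lower, and grey points the 7457 not past the threshold.

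Lo_f3p60_1424_transcript3847_g1, of 1424 nt, rose from 33.8 ± 4.83 FPKM in controls to 759.8 ± 22.0 FPKM in drought libraries (SD, n = 3 each), a log2 change of 4.46 ± 0.19 (SE, limma adjusted p = 0.000132). Lo_f3p34_1325_transcript19421_g1, of 1325 nt, rose from 0.357 ± 0.046 to 86.1 ± 12.1 FPKM, a log2 change of 5.99 ± 0.27 (SE, limma adjusted p = 0.000132). The size of this second change depends on the pseudocount, with a log2 change of 3.21 at a pseudocount of 10 and 7.55 at 0.1. Lo_f2p60_1054_transcript6334_g3, of 1054 nt, had 68.96, 68.43 and 73.41 FPKM in the controls and was listed at 0 in all 3 drought libraries. Lo_f3p60_883_transcript26020_g4, of 883 nt, had 89.89, 114.39 and 65.15 FPKM in the controls and was also listed at 0 in all 3 drought libraries. Both fallen transcripts had a limma adjusted p of 0.000132, and no fold is given against values of 0. A listed 0 can be a failed estimate where similar transcripts share fragments, which could not be examined here.

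**Figure D3:**
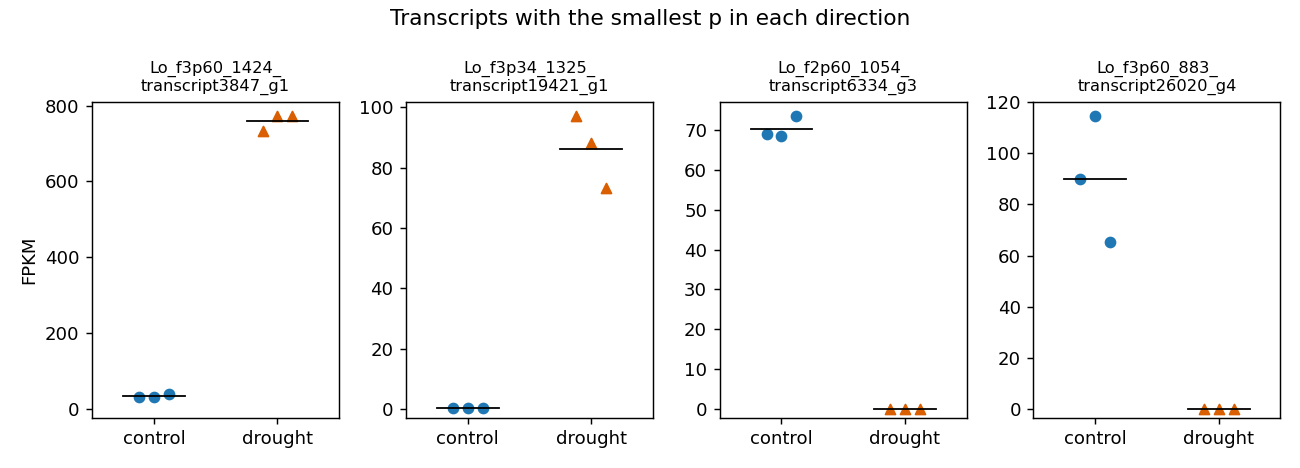
FPKM of the 2 risen and 2 fallen transcripts with the smallest p in each library, on linear axes that differ between panels, with circles for controls, triangles for drought and a line at each group mean. All drought values lie above all control values for the risen pair, and all drought values are 0 for the fallen pair.

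Some transcripts were listed above 0 in one group alone, more than in any other split of the libraries. There were 16 transcripts listed at 0 in all controls with at least 1 FPKM in all drought libraries, reaching a mean of 686.6 FPKM (median 13.9). There were 13 listed at 0 in all drought libraries with at least 1 FPKM in all controls, reaching 89.8 FPKM (median 10.1). The other 9 splits gave at most 5 of either kind, but they mix the groups, so a group difference itself keeps their counts low.

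The number of detected transcripts and the share of FPKM in the most abundant ones were compared next. Controls had 9611 ± 15.7 transcripts above 0 (SD, n = 3) and drought libraries 9607 ± 67.0 (exact two-sided permutation p = 1, smallest possible 0.1). The 100 most abundant transcripts held 32.4% ± 7.74 of FPKM in controls and 26.2% ± 2.35 in drought libraries (SD, n = 3, exact permutation p = 0.2). The 10 transcripts with the highest mean over all libraries held 9.59% ± 3.21 in controls and 6.16% ± 0.75 in drought libraries (SD, n = 3), with every control above every drought library (exact permutation p = 0.1, the smallest possible). That separation was lost with each library's own top 10, where drought 1 held 8.30% and control 2 held 8.09%. For the 1000 transcripts with the highest mean the difference, drought minus control, was -2.73 percentage points (exact permutation p = 0.8), and for each library's own top 100 it was -6.07 (exact permutation p = 0.6). Control 3 set the control spread of the 100, with 41.4% against 28.3% and 27.7% in controls 1 and 2. Drought minus control was -6.28 percentage points over all libraries and -1.81 without control 3. With 3 libraries per group, none of these results shows that the groups were alike.

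Large changes made up a bigger share of the short transcripts than of the long ones, described without a test because transcripts are not independent. A called change of at least 4-fold was found in 12.4% of the 1843 tested transcripts under 800 nt, in 8.52% of 2652 transcripts of 800 to 1199 nt, in 6.09% of 2266 transcripts of 1200 to 1699 nt, and in 3.68% of 2556 transcripts of 1700 nt and over. Transcripts under 800 nt fell more often (241) than they rose (177), and those of 800 to 1199 nt rose more often (316) than they fell (262). With a length trend between libraries removed, described next, the first difference was gone (264 rose, 262 fell) and the second stood at 440 and 366. That removal also takes out each library's offset, so length alone is not shown to be the reason. Calls of any size made up 22.7%, 21.8%, 22.6% and 13.8% of these classes from short to long, and 28.5%, 30.4%, 32.3% and 30.6% with the trend removed. Median lengths were 1177 nt for risen, 1108 nt for fallen and 1255 nt for the remaining transcripts.

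Levels also varied with length between libraries of the same group. Transcripts of 2500 nt and over had a median log2 deviation from the mean of all libraries of -0.82 in control 3 and -0.52 in drought 1. Control 3 lay below that mean in every length class (-0.08 under 500 nt), so part of its -0.82 may be a library-wide offset. The same class stood at 0.28 and 0.35 in controls 1 and 2 and at 0.43 and 0.29 in drought 2 and 3. Drought 3 had the opposite slope, with -0.36 in transcripts under 500 nt. The split into libraries with and without the loss of long transcripts crosses the treatment groups. Within the 4 libraries without that loss, which are not free of length trends, 3218 transcripts passed (1360 higher, 1858 lower). Its control arm is again controls 1 and 2 alone, and the part this plays in the count was not separated. The pair that shows the loss has 1 library per group and allows no test. With the trend removed from every library, 2847 transcripts passed (1466 higher, 1381 lower), including 1786 of the 1860. This removal also rescales each library. Quantile normalization, which uses no lengths, gave 2393 calls, so the rise in calls cannot be credited to length alone. With a term for the 2 libraries that show the loss, 2954 passed (1539 higher, 1415 lower). The term uses no lengths and takes up any difference these 2 libraries share, so these calls cannot be credited to length alone. With the trend removed, called 4-fold changes were found in 12.1% of transcripts under 800 nt and in 3.99% of those of 1700 nt and over.

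**Figure D4:**
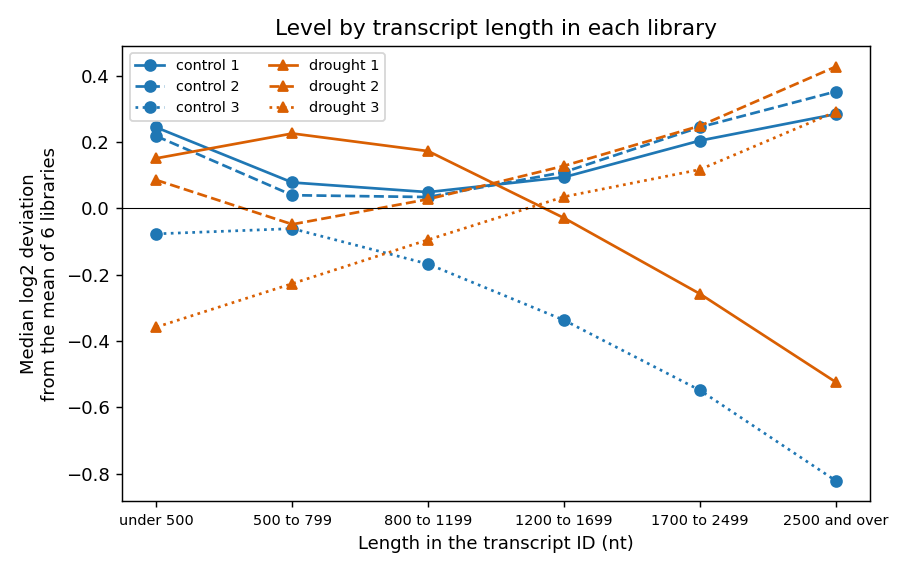
Median log2 deviation of each library from the mean of the 6 libraries, by class of transcript length in nt, with one line per library. Control 3 and drought 1 fall to -0.82 and -0.52 in transcripts of 2500 nt and over, and the other 4 libraries lie between 0.28 and 0.43 there.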

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

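The settings with estimated fragments, other pseudocounts, quantile normalization, no mean-variance trend, averaged controls and the length trend were chosen after seeing the data. The count of 1860 transcripts past the threshold stayed within 1.5 times under 16 of 25 alternatives and the count of 1635 with at least a 2-fold change under 19 of 25. Leaving out each library gave 742 to 2623 calls and 742 to 2022 calls of at least 2-fold. The lowest came without drought 2 and the highest without control 3, and each such comparison leaves an arm of 2 libraries, which without control 3 are the closely spaced controls 1 and 2. Averaging controls 1 and 2 gave 919 calls, all of at least 2-fold, and a threshold of 0.01 gave 701. A test against a 1.5-fold change gave 722. Removing the length trend gave 2847 calls, a term for the 2 libraries that lose long transcripts 2954, and the other 4 libraries alone, again with controls 1 and 2 as the only controls, 3218, and the median spread within groups fell from 0.398 to 0.304 on the log2 scale when the trend was removed. The removal also takes out each library's offset, so neither the 2847 calls nor the fall in spread can be credited to length alone. The same holds for the 2954 calls, since that term uses no lengths. Removing the trend and averaging controls 1 and 2 together gave 1386. None of the 1860 called transcripts changed direction under any of the 25 alternatives in which it was tested, 3 of which did not test all of them. For most settings this was fixed beforehand. The called transcripts do not overlap between groups, so leaving out or averaging libraries or another pseudocount cannot turn them. Another filter, threshold, variance estimate or block leaves the log2 change as it is. Other scalings, quantile normalization, estimated fragments and length-trend removal could have turned a direction. With 1635 of the 1860 changed at least 2-fold, the scalings were unlikely to turn most of them. The log2 change of Lo_f3p34_1325_transcript19421_g1 ran from 3.21 (pseudocount 10) to 7.79 (estimated fragments). The 4 named transcripts kept direction and call in all 100 repeats, with limma adjusted p up to 0.00429. They were chosen for the smallest p and no overlap in these same libraries, so this was close to assured. The repeats at a threshold of 0.01 reuse the main fit. With the replicate number as a block, which the labels do not describe as a pairing and the deviations did not bear out, 1428 transcripts passed, 1358 of them with at least a 2-fold change. The scalings gave 1588 to 2182 calls. Drought minus control in detected transcripts was -4.33, turned to 4.17 without control 1 and 34.0 without drought 3, and ranged from -28.0 to 34.0 over the libraries left out. The cause was not tested. The difference in the share of the 100 most abundant transcripts ranged from -8.66 to -1.81 percentage points over the libraries left out and kept its direction. In simulated data with this spread, 3 libraries per group and 200 changed transcripts, 10% of 2-fold changes were called. That share depends on how many transcripts change and may differ in these data. How depth limits low transcripts was not simulated.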

Other observations

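All tests in this part were chosen after the results were seen. Values listed at 0 were most frequent among short transcripts, for which the fitted length offset of 280 to 290 nt leaves little effective length: 39.8% of the 940 transcripts under 500 nt were listed at 0 in all 6 libraries, 24.9% of the 1999 of 500 to 799 nt, and between 14.5% and 16.4% in each class from 800 nt upward. A listed 0 does not show that a transcript was absent. The most abundant 10 transcripts of each library held 14.6% of FPKM in control 3 and between 6.44% and 8.30% in the other 5.

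No other split of the 6 libraries into 3 and 3 gave as many calls. The real split gave 1860 and the highest of the others 2, and for changes of at least 2-fold 1635 and 2. The real one was thus 1 of 10 splits, which are too few for a share under 0.05. The other splits also mix control and drought libraries in each arm. A difference between the groups then adds to their spread and holds down their calls, so they do not show what no effect would give.

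Control 3 and drought 1, which are from different groups, shared a loss of signal from long transcripts. Relative to the mean of the 6 libraries, the log2 slope per doubling of length was -0.27 and -0.30 in these 2 and 0.08 to 0.26 in the other 4, where centring forces part of the rise. The gap in slope was 0.34 with and without the 100 most abundant transcripts, which decides nothing because rescaling moves a library's values alike. A different effective length in the FPKM division is argued against. The fitted offsets would shift a transcript of 2500 nt by 0.0065 against a gap of 0.81. The offsets show only the length by which values were divided, so a difference in fragment size not used there was not tested. Group mean slopes were 0.0499 apart, with ranges of 0.39 and 0.56 within groups. The pattern was picked with 1 such library in each group, so these values restate it and are no test of watering. The watering label alone does not tell these 2 libraries from the rest of their groups. RNA integrity or library preparation may be the source; neither was tested, since the files hold no positions along transcripts.

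Controls 1 and 2 were closer to each other than any other pair. Repeat runs of 1 library stay open: the variance was 2.47 times counting noise (95% interval 2.34 to 2.64), but shared fragments and PCR copies raise this ratio and no known repeat run is at hand for comparison. Libraries from 1 plant or RNA pool also cannot be told apart from separate plants that were alike: 118 transcripts were at least 2-fold apart, against 718 to 2510 in the other same-group pairs, and the labels name no plants. If the libraries are not independent, the 919 calls with both averaged may be the safer count.

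Drought 3 lay nearer the controls, most clearly in risen transcripts. The 95% intervals in this paragraph come from 2000 bootstrap draws over transcripts. They carry no spread between libraries, and transcripts are not independent replicates. In the 207 transcripts with at least 20 FPKM in drought 1 and over 8-fold above every control, drought 3 was lower than drought 2 by a median log2 difference of -1.34 (95% interval -1.71 to -1.17), in the 174 chosen likewise on drought 2 it was lower than drought 1 by -1.72 (-1.95 to -1.29), and in the 85 chosen on drought 3 itself the change was 4.28, against 4.98 and 4.89 in drought 1 and 2. Transcripts chosen on drought 1 with at least 20 FPKM in every control and a fall of over 8-fold were higher in drought 3 than in drought 2 by 0.960 (0.760 to 1.25) and those chosen on drought 2 higher than in drought 1 by 0.900 (0.568 to 1.09), but those chosen on drought 3 fell most in drought 3 (-4.69, against -2.63 and -3.17), so a smaller fall and the effect of the choice cannot be told apart. Control RNA mixed into drought 3 is argued against as the whole source. The fallen transcripts would need 6.74% of it (3.55% to 7.76%) and the risen ones 71.8% (64.9% to 78.0%). A small admixture stays open, and the risen share also strayed to -43.6% for drought 1. The sets for drought 3, here and for the length trend, were chosen for changes of over 8-fold in both drought 1 and drought 2. That choice alone can place drought 3 nearer the controls. Drought 3 showed 0.691 of the rise and 0.694 of the fall of drought 1 and 2. With the length trend removed, it showed 0.718 and 0.657. The choice alone could hold these below the full change, so they do not decide on the trend, though its removal moved them little. A smaller rise in the material of drought 3 may account for the risen part, as a hypothesis found and tested on the same libraries.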
